A study of Homo sapiens with 12 samples.

How the data were processed

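RNA was sequenced from 12 cultures of a conditionally immortalized human podocyte line. Podocytes are the epithelial cells that cover the outside of the glomerular capillaries of the kidney. The line carries a temperature-sensitive SV40 T gene and was differentiated at the temperature that inactivates it. Cultures then received DMSO, cyclosporine A (CSA), tacrolimus (TAC) or voclosporin (VCS) at 100 nM for 24 h, with 3 replicates in each of 4 groups. The 3 compounds inhibit calcineurin, the calcium-dependent phosphatase that activates NFAT transcription factors. VCS is a structural analog of CSA and TAC is a macrolide. What the replicates were (wells, passages or days) is not given in the sources used here.

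Per the labels, the libraries were poly(A)-selected and sequenced on an Illumina instrument, with in-line UMIs and added ERCC RNAs. The submitters' processing notes name Salmon and the GRCh38 genome, without versions or an annotation release. The deposited table gives whole numbers per gene and library; their unit was read to be expected counts, rounded by the authors. No normalization by the authors was seen, since the library totals differ. Whether the UMIs were collapsed is not stated, so a count is not known to be an independent molecule, and intervals and floors cover counting error only. The table held 62262 genes by Ensembl identifier, of which 22339 had no count in any library. No spike-in rows were among them, so scaling on spike-ins was not run. Symbols were found for 62252 identifiers. Positions, gene types and overlaps came from GENCODE 29 on GRCh38, in which 18900 of the 19784 tested genes had an entry. Whether the counting used the strand of the reads is not stated.

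Library totals ran from 28808213 to 36077072 counts. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3, with its minimum count of 10, which left 19784 genes. Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model over all 12 libraries, with group as the only term and 8 residual degrees of freedom. Each inhibitor was compared with DMSO, each pair of inhibitors was compared, and the mean of the 3 inhibitors was compared with DMSO. A further test asked whether any of the 4 groups differed. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Levels are edgeR's CPM, counts scaled to the size of the library, with the SD over 3 libraries. Log2 fold changes are given with their SE, and each adjusted p is from edgeR unless another test is named. All p-values are two-sided.

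The comparisons, the tests, the alternatives and 45 gene lists with 1013 genes were fixed before the data were examined, and 965 of the listed genes were tested. The lists covered podocyte genes, calcineurin and NFAT, pathways that calcineurin inhibitors are known or proposed to touch, general cell states, matrix, and markers of other cell types. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 45 lists within a comparison. Camera compares a list with the other genes. The same test with an estimated correlation and the rotation test fry are given beside it; fry asks whether the genes of a list move, on balance, one way. A list's score in a library is the mean log2 CPM of its tested members with a prior count of 2. Score differences carry a 95% interval from the pooled spread within the 4 groups and an exact permutation test. Exact tests of 3 against 3 libraries cannot give a p below 0.1.

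Genes were named by a rule fixed in advance. It took RCAN1, NPHS1, SYNPO, WT1, TRPC6, ACTN4, PPP3CA, FKBP1A and PPIA in every case, and a further gene that is not reported here. It added genes past the threshold whose libraries did not overlap between the groups, up to 10 per direction against DMSO and up to 5 per direction between inhibitors. Where none passed, it took the 5 smallest p-values in each direction, and from each list up to 4 members. Genes without a symbol or with a mean log2 CPM under 1 were not to be named. SFTPA1, H2BC26, LINC02593, ID4, HEY1 and genes printed by identifier fall outside this rule and were named after their values were seen, as were other genes where the text says so.

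The alternatives were size factors by the median ratio (RLE) in edgeR, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared, replicate number as a block, and each library left out in turn. Fits without the 4 libraries numbered 3 and with robust estimation of the spread were added after seeing the data.

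The gene test for TAC against DMSO was tested on counts simulated for all 12 libraries, from the mean levels over these libraries and the fitted spread. It recovered 25.4% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold. It made 4 false calls with changed genes present and 0 calls when no change was simulated. The simulated genes were independent, so the effect of correlation between genes was not tested there. The simulation also held 67, 67 and 66 changed genes at these folds, of which 17, 53 and 65 were recovered. In the data 7 genes passed for TAC against DMSO. More changed genes ease the adjusted threshold, so recovery in the data is likely lower than these shares. Other groupings of the libraries were fitted to count how often they gave as many calls.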

Results

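The series asks how calcineurin inhibitors change the transcriptome of differentiated human podocytes in culture. Poly(A) RNA was measured in 4 groups of 3 libraries: DMSO, CSA, TAC and VCS, each inhibitor at 100 nM for 24 h. Total counts ran from 28808213 in VCS replicate 3 to 36077072 in CSA replicate 3. Between 28419 and 29296 genes had counts in a library. MT-CO1, a mitochondrial subunit of cytochrome c oxidase, was the most abundant gene in every library and took 1.65 to 3.89% of its counts. Mitochondrial transcripts took the largest share in the library numbered 3 of every group: 10.8% in DMSO, 9.68% in CSA, 10.1% in TAC and 13.4% in VCS, against 5.82 to 8.12% in the other libraries. The first principal component held 28.2% of the variance, and the DMSO, TAC and VCS libraries numbered 3 lay at its positive end.

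NPHS1 and TRPC6, genes of the podocyte slit diaphragm, were nearly silent in all groups. NPHS1, which encodes nephrin, had 1 to 11 counts per library, and the calcium channel gene TRPC6 had 0 to 6; neither was tested. WT1, a podocyte transcription factor, was at 0.854 ± 0.219 CPM in DMSO (SD, n = 3) and at 1.22 ± 0.31 in TAC (log2 0.51, SE 0.32, adjusted p = 0.92). Cytoskeletal genes were well expressed. ACTN4 was at 1429 ± 66.5 CPM in DMSO, and SYNPO, which encodes the actin-associated protein synaptopodin, was at 46.3 ± 5.38. SYNPO was at 59.9 ± 6.68 in CSA, 55.9 ± 5.7 in TAC and 56.7 ± 7.28 in VCS, with adjusted p-values of 0.939, 0.92 and 0.963 against DMSO.

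No change of calcineurin's own circuit was detected with group as the only term. RCAN1, a calcineurin inhibitor protein and a classical NFAT target, was at 159.6 ± 7.62 CPM in DMSO, 154.6 ± 3.93 in CSA, 166.0 ± 7.07 in TAC and 168.9 ± 14.8 in VCS. The 95% intervals of its log2 fold change were -0.23 to 0.14 for CSA, -0.13 to 0.25 for TAC and -0.11 to 0.27 for VCS. PPP3CA, a catalytic subunit of calcineurin, differed from DMSO by 0.07, 0.07 and 0.17 (SE 0.07 each). FKBP1A, the binding protein of tacrolimus, differed by -0.09, 0.00 and -0.06 (SE 0.11 each), and PPIA, the binding protein of cyclosporine, by -0.18, 0.01 and -0.06 (SE 0.11 each). None of these genes passed. Of 22 measured NFAT targets, none passed over all genes or adjusted over the list alone against DMSO. With replicate number as a block, the target IL11, named after its value was seen, passed over all genes in TAC against DMSO, higher. Their median log2 fold changes were -0.05 in CSA, -0.06 in TAC and 0.06 in VCS, with camera adjusted p-values of 0.695, 0.536 and 0.661. Members went both ways: in TAC 9 were above 0 and 13 below, and 2 in each direction had an unadjusted p under 0.05. The NFAT score differed from DMSO by -0.042 (95% interval -0.288 to 0.205), -0.061 (-0.307 to 0.186) and 0.054 (-0.193 to 0.3). The 24 measured calcineurin and NFAT proteins (camera adjusted p = 0.849, 0.208 and 0.187) and the 29 immunophilins (0.176, 0.658 and 0.297) did not pass either.

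The comparison of CSA with DMSO asks what cyclosporine A changes at this dose. Genes switched on by ATF4, the transcription factor of the integrated stress response, lay higher in CSA (camera adjusted p = 9.72e-12; adjusted p = 0.071 with an estimated correlation and 0.0457 by fry). Of 28 measured members, 25 had a positive log2 fold change (median 0.24). The amino acid transporter gene SLC7A5 was at 103 ± 9.53 CPM against 76.3 ± 6.88 in DMSO (log2 0.44, SE 0.11), the serine synthesis gene PHGDH differed by 0.37 (SE 0.11), and the alanyl-tRNA synthetase gene AARS1 by 0.31 (SE 0.10). No member passed over all genes, and 1 (SLC7A5) was higher when adjusted over the list alone.

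Endoplasmic reticulum and matrix genes also lay higher in CSA by the preset test, and did not pass with an estimated correlation (adjusted p = 0.619). In the unfolded protein response list, 22 of 25 members were above 0 (median 0.19), and DNAJB9, an endoplasmic reticulum co-chaperone, was at 26.7 ± 4.36 CPM against 18.4 ± 1.36 (log2 0.54, SE 0.12, adjusted p = 0.708). DNAJB9 was the 1 member higher adjusted over the list alone. Of 19 glomerular basement membrane genes 16 were above 0, among them COL18A1 (0.29, SE 0.12) and AGRN (0.31, SE 0.13), as were 20 of 26 interstitial matrix genes, among them TNC (0.53, SE 0.21). Positive values were found for 21 of 25 slit diaphragm and foot process genes, 18 of 22 focal adhesion genes, 16 of 22 TGF-beta targets, 29 of 34 lysosomal genes, 21 of 27 NRF2 targets and 15 of 19 fatty acid synthesis genes. Interferon-stimulated genes lay lower: 30 of 37 were below 0 (median -0.23), with IFI44L at 39.0 ± 7.74 CPM against 62.3 ± 11.2 (log2 -0.68, SE 0.17, adjusted p = 0.939). No member of these lists passed over all genes, and apart from DNAJB9 none passed adjusted over the list alone. In all, 11 of 45 lists passed with the preset correlation (largest camera adjusted p 0.0341); for the 10 besides the ATF4 list, adjusted p = 0.619 with an estimated correlation. Without CSA 3 the calls on the slit diaphragm, TGF-beta, interstitial matrix, basement membrane, lysosomal and fatty acid lists were lost (adjusted p 0.0989 to 0.451), and without CSA 2 that on NRF2 (0.292).

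Across all genes 2 of 19784 passed in CSA against DMSO, and 741 had an unadjusted p under 0.05, where 989 are expected by chance. SFTPA1 (ENSG00000122852), a lung surfactant protein gene at chromosome 10, 79610939 to 79615455, fell by 4.19 on the log2 scale (SE 0.50, adjusted p = 0.0258). It was at 0.201 ± 0.0767 CPM in CSA and 3.72 ± 0.618 in DMSO. H2BC26 (ENSG00000196890), a histone H2B gene on chromosome 1, rose from 2 counts summed over the DMSO libraries to 93 in CSA (adjusted p = 0.0306). Its ratio was 44.6, with a 95% counting interval of 12 to 373. SFTPA2, KRT5 and KRT14, transcripts of lung and basal epithelia, were low in the same libraries, with log2 fold changes of -2.50 (SE 0.43), -2.50 (SE 0.48) and -3.19 (SE 0.62) that did not pass (adjusted p = 0.403, 0.518 and 0.518). With replicate number as a block SFTPA2 and KRT5 passed. SFTPA1 and SFTPA2 are near copies, as are histone genes, so the assignment of reads among copies is uncertain. RNA or reads of airway epithelium in some libraries is a candidate explanation for SFTPA1, SFTPA2, KRT5 and KRT14. It stays open in every comparison where SFTPA1 is named. SFTPA1 lost its call without DMSO 1, DMSO 3, any CSA library or TAC 2, and H2BC26 without these, TAC 1, TAC 3 or VCS 1, with adjusted p up to 0.27; without the 4 libraries numbered 3 no gene passed and 6 lists did. DESeq2 gave 8 genes, 4 in each direction. With replicate number as a block 6 genes passed and 2254 had an unadjusted p under 0.05. The count under 989 without the block is therefore no sign that change was absent.

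**Figure D1:**
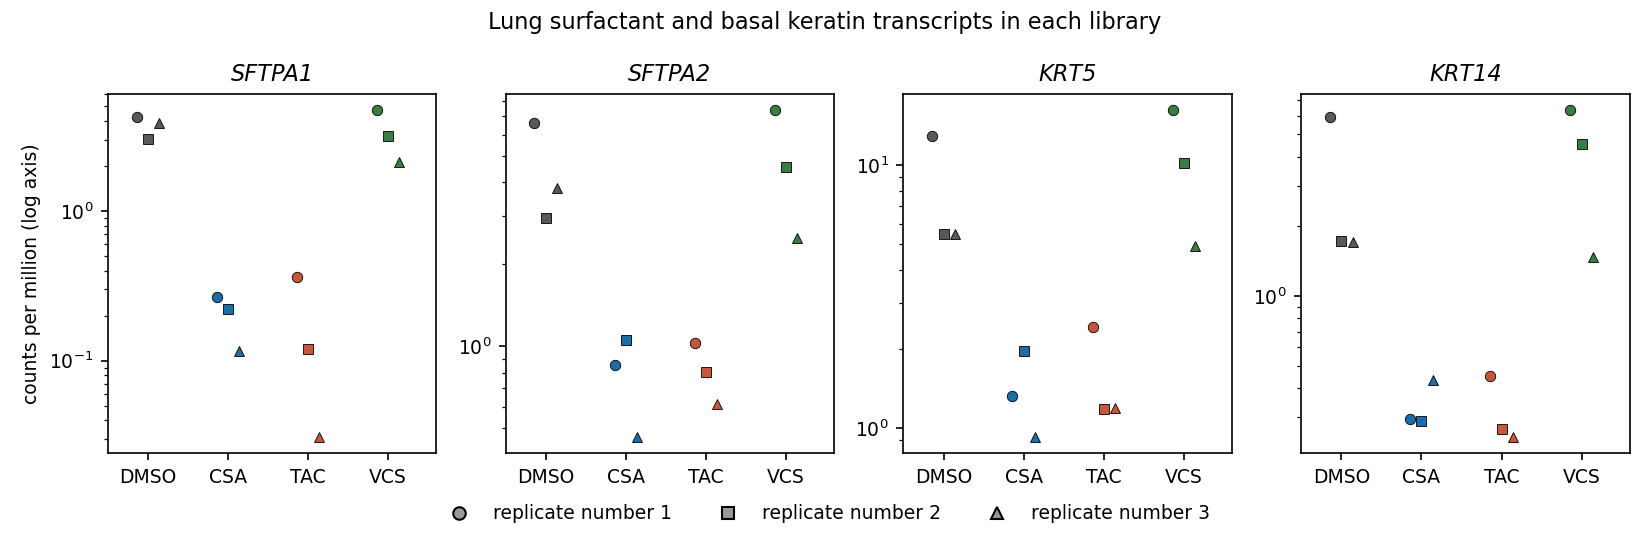
Level in CPM (log axis) of SFTPA1, SFTPA2, KRT5 and KRT14 in each library, 1 point per library with the marker giving the replicate number. SFTPA1 lay between 0.031 and 0.363 CPM in the CSA and TAC libraries and between 2.11 and 4.74 CPM in the DMSO and VCS libraries. Whether airway RNA or reads in some libraries set these levels stays open.

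The comparison of TAC with DMSO asks what tacrolimus changes. Genes of the fixed list of BMP-SMAD targets lay mostly higher in TAC. A set of 22 genes picked as targets outside that list, tested later, had a median of -0.057 for TAC minus the 9 other libraries. That set also holds receptors and antagonists of the pathway. ID1, a helix-loop-helix repressor that BMP induces, rose from 39.6 ± 5.64 to 91.1 ± 3.86 CPM (SD, n = 3; log2 1.20, SE 0.18, adjusted p = 0.045). ID3 was at 139.4 ± 11.6 CPM against 93.4 ± 4.79 (log2 0.58, SE 0.09, adjusted p = 0.0522), the inhibitory SMAD gene SMAD6 at 15.8 ± 0.813 against 10.3 ± 0.72 (0.61, SE 0.10, adjusted p = 0.0861) and SMAD9 at 11.6 ± 1.67 against 6.49 ± 0.595 (0.84, SE 0.15, adjusted p = 0.112). Of 18 measured members, 1 passed over all genes and 8 were higher adjusted over the list alone: these 4, and ATOH8 (0.96), SMAD7 (0.47), ID4 (0.94) and ID2 (0.63), named after their values were seen. With replicate number as a block 6 of the 18 passed over all genes. Members that stayed near DMSO include BAMBI (0.12, SE 0.13) and GREM1 (0.11, SE 0.25).

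The BMP-SMAD list passed camera (adjusted p = 1.3e-17) and did so with an estimated correlation (adjusted p = 0.00723) and by fry (adjusted p = 0.00855). Its score was 3.72 ± 0.094 in TAC against 3.30 ± 0.14 in DMSO, and all 3 TAC libraries were above all 3 DMSO libraries (exact permutation p = 0.1, the smallest that 3 against 3 allow). The difference was 0.415, with a 95% interval of 0.205 to 0.625. Of the lists called in any comparison it was the 1 list that passed with an estimated correlation. Its call against DMSO held in all 12 fits that left out a library (adjusted p up to 1.26e-10, without TAC 3). ID1 itself passed in 4 of those 12 fits; it was lost without any DMSO or TAC library, CSA 2 or VCS 2 (adjusted p up to 0.235).

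**Figure D2:**
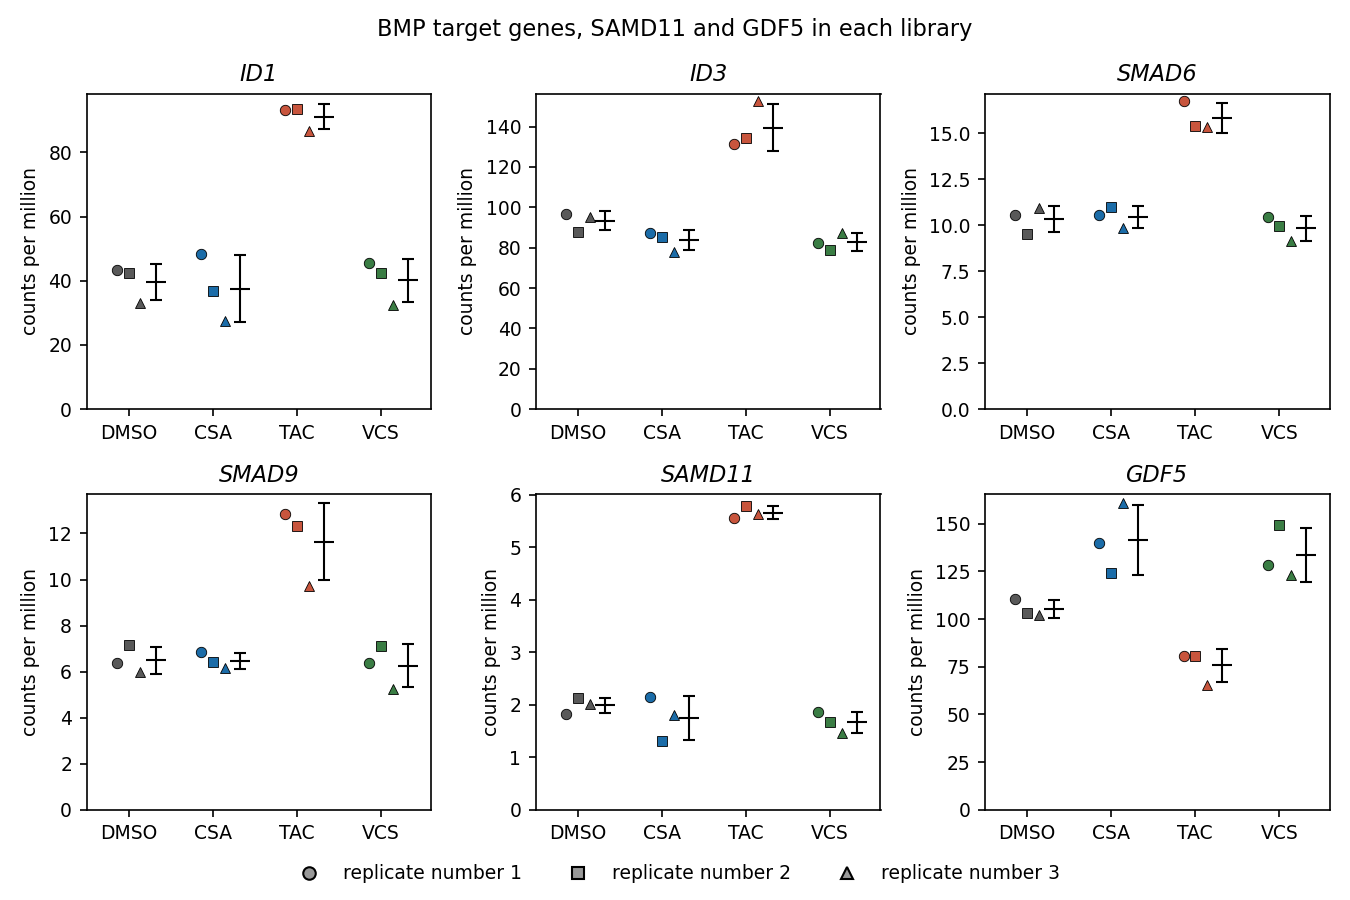
Level in CPM of the BMP targets ID1, ID3, SMAD6 and SMAD9 and of SAMD11 and GDF5 in each library; points are libraries with the marker giving the replicate number, and the bar is the mean ± SD of 3. ID1 was at 86.7 to 93.5 CPM in the TAC libraries and at 27.5 to 48.3 CPM in the 9 others.

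Other groups moved in TAC with the preset correlation alone. TGF-beta targets lay higher, with 17 of 22 above 0 and 4 higher adjusted over the list alone: TGFBI (1268 ± 58.8 CPM against 862.4 ± 58.8, log2 0.56, SE 0.10), BHLHE40 (0.37), SMAD7, which the BMP list also holds, and SKIL (0.39). Cell cycle genes were above 0 in 36 of 43, among them the kinetochore motor gene CENPE (0.37, SE 0.09) and CCNB2 (0.43, SE 0.17). NF-kB and inflammatory genes were below 0 in 29 of 32, with IL1B at 2.81 ± 0.692 CPM against 4.91 ± 0.924 (log2 -0.81, SE 0.22, adjusted p = 0.89), TNF at -0.63 (SE 0.19) and VCAM1 at -0.58 (SE 0.19). CREB targets (15 of 19), glucocorticoid receptor targets (16 of 20) and NRF2 targets (20 of 27) lay mostly above 0, while interferon-stimulated genes (34 of 37) and endothelial markers (12 of 14) lay mostly below. Apart from the 4 TGF-beta targets, no member of these 8 lists passed over all genes or adjusted over the list alone. For the NF-kB list the camera adjusted p was 9.56e-11, and adjusted p = 0.139 with an estimated correlation. For the endothelial list these were 0.00236 and 0.661. For the other 6 the camera adjusted p was at most 0.0245, and adjusted p = 0.571 with an estimated correlation. The endothelial call was lost without TAC 3 (adjusted p 0.32), and the CREB, glucocorticoid and NRF2 calls without DMSO 3 (0.0523, 0.0681 and 0.165).

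**Figure D3:**
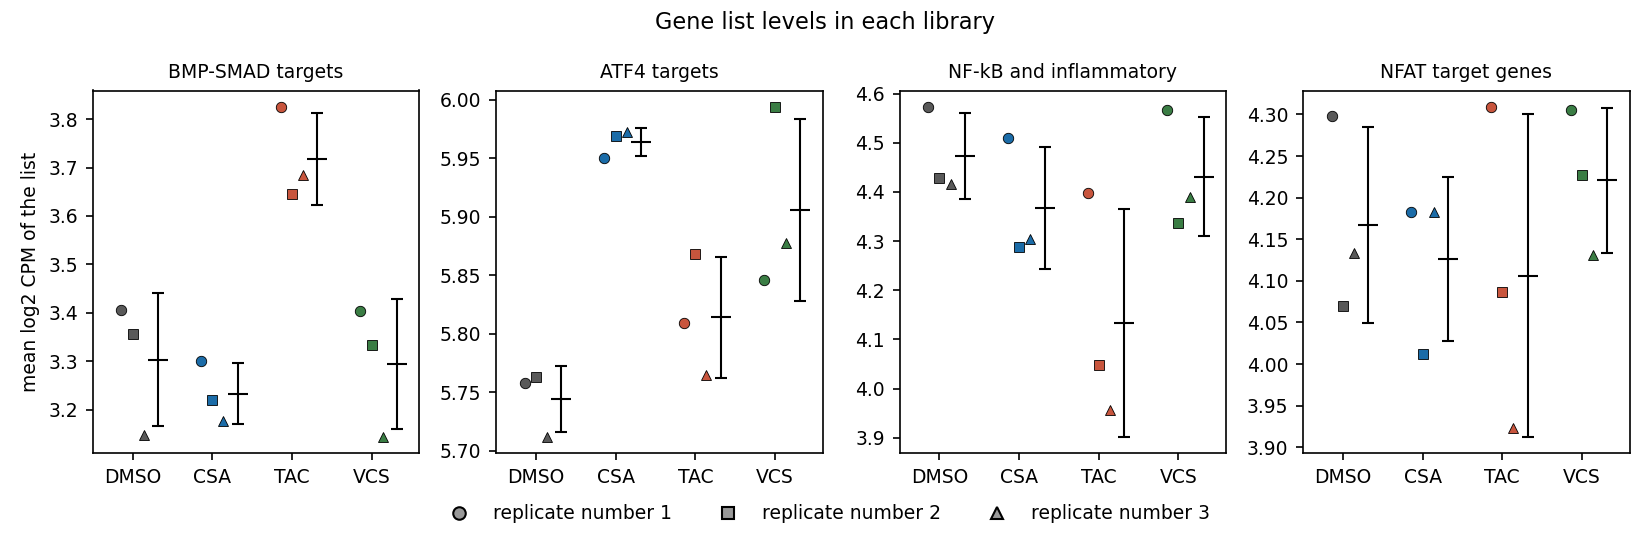
Mean log2 CPM of the tested members of 4 gene lists in each library; points are libraries with the marker giving the replicate number, and the bar is the mean ± SD of 3. The BMP-SMAD score was 3.645 to 3.825 in the TAC libraries and 3.144 to 3.405 in the 9 others, and the NFAT target score overlapped among all 4 groups.

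Of 19784 genes, 7 passed in TAC against DMSO, 5 higher and 2 lower, and 919 had an unadjusted p under 0.05 against 989 expected by chance. SAMD11 (ENSG00000187634), on chromosome 1 from 923928 to 944581, rose from 1.99 ± 0.15 to 5.66 ± 0.117 CPM (log2 1.51, SE 0.19, adjusted p = 0.0143). LINC02593, a noncoding RNA gene 2912 bp away, rose by 1.68 (SE 0.23). SAMD11 overlaps NOC2L on the other strand. The pseudogene ENSG00000269706, 1111 bp from the chorionic gonadotropin gene CGB8, rose by 2.08 (SE 0.27), and H2BC26 rose from 2 counts to 82 (ratio 39.5, 95% counting interval 10.6 to 332). SFTPA1 fell by 4.41 (SE 0.51), to 0.171 ± 0.172 CPM, where airway RNA or reads in some libraries again stay a candidate. ENSG00000196656, a processed pseudogene inside ANK2, had 716 counts over the DMSO libraries and 1 in TAC (ratio 743, 95% counting interval 133 to 29400), with 63 to 409 counts in single DMSO libraries. The gene it was copied from was not examined, so the assignment of reads to ENSG00000196656 is uncertain in every comparison. The counting interval does not cover this. No gene passed without TAC 2 or without TAC 3, and 10 passed without VCS 1 or VCS 3. With only these 2 groups in the fit 1 gene passed. DESeq2 gave 34 genes, which held all 7. With replicate number as a block 41 genes passed, 23 higher and 18 lower, and 2597 had an unadjusted p under 0.05.

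The comparison of VCS with DMSO asks what voclosporin changes. Genes of the ATF4 list again lay mostly higher, 25 of 28 above 0 (median 0.18; camera adjusted p = 7.8e-07; adjusted p = 0.333 with an estimated correlation), with the cystine transporter gene SLC7A11 at 13.5 ± 2.41 CPM against 8.96 ± 2.13 (log2 0.59, SE 0.21) and PSPH at 0.25 (SE 0.09). CEBPB, a member that went the other way, was at -0.35 (SE 0.15). DNAJB9 was at 26.02 ± 1.77 CPM against 18.4 ± 1.36 (log2 0.50, SE 0.12, adjusted p = 0.963) and was higher adjusted over the unfolded protein response list alone. HEY1, a target of BMP and Notch signalling, was at 1.39 ± 0.263 CPM against 0.686 ± 0.167 (log2 1.01, SE 0.27, adjusted p = 0.963) and passed adjusted over either of these lists alone.

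Matrix and adhesion genes lay higher in VCS by the preset test, and did not pass with an estimated correlation (adjusted p = 0.931). Above 0 were 25 of 26 interstitial matrix genes (TNC 0.62, SE 0.21), 18 of 19 basement membrane genes (COL4A1 0.31, SE 0.16), 20 of 22 focal adhesion genes (CAV1 0.28, SE 0.09), 20 of 25 slit diaphragm and foot process genes and 21 of 26 calcium handling genes (S100A4 0.90, SE 0.28). Interferon-stimulated genes were below 0 in 28 of 37, with STAT2 at -0.35 (SE 0.11). Together with the ATF4 and unfolded protein response lists, 8 lists passed with the preset correlation (largest camera adjusted p 0.0169). For the calcium list adjusted p = 0.916 with an estimated correlation, and for the 6 besides it and ATF4 it was 0.931. No member of these 8 lists passed over all genes, and DNAJB9 alone passed adjusted over the list alone. The interferon call was lost without VCS 3 (adjusted p 0.479) and held without all 4 libraries numbered 3 (0.000132). Without DMSO 2 the basement membrane (0.32), unfolded protein response (0.194), interstitial matrix (0.116) and calcium (0.116) calls were lost, and without VCS 1 the slit diaphragm (0.171) and focal adhesion (0.0613) calls.

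In VCS against DMSO 1 gene passed and 647 had an unadjusted p under 0.05. The pseudogene ENSG00000196656 had 716 counts over the DMSO libraries and 0 in VCS, at least 76.6-fold lower taking a floor of 3 counts per library (adjusted p = 0.0406). The assignment of reads to it is uncertain here too. Its call was lost without DMSO 2, any CSA or TAC library, or VCS 2 (adjusted p up to 0.279). No gene passed with only these 2 groups in the fit, nor with robust estimation. Without VCS 1, 8 genes passed: this pseudogene, lower, and 7 higher whose counts in VCS 1 lay under those in VCS 2 and VCS 3. The mucin gene MUC5B had 74 counts in VCS 1 against 417 and 387 in VCS 2 and VCS 3, with 65 to 89 in DMSO, 133 to 150 in CSA and 157 to 174 in TAC (log2 2.52 without VCS 1, adjusted p = 5.27e-05). The receptor gene IL13RA2 had 13 counts in VCS 1 against 112 and 109, with 14 to 20 in DMSO, 47 to 63 in CSA and 40 to 53 in TAC (log2 2.73 without VCS 1, adjusted p = 0.00134). For these 2 genes, named after their values were seen, VCS 1 lay near DMSO and under all other inhibitor libraries, while for ENSG00000196656 it had 0 counts, as VCS 2 and VCS 3 did, against 63 or more in each DMSO library. DESeq2 gave 7 genes. With replicate number as a block 0 genes passed, while 2179 had an unadjusted p under 0.05.

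No gene passed in all 3 comparisons with DMSO. H2BC26 and SFTPA1 passed in CSA and in TAC, and ENSG00000196656 in TAC and in VCS. For the mean of the 3 inhibitors against DMSO 2 genes passed, SFTPA1 (log2 -2.92, SE 0.33, adjusted p = 0.00688) and ENSG00000196656, both lower, and 725 had an unadjusted p under 0.05. SFTPA1 was at 3.34 ± 1.32 CPM in VCS and 3.72 ± 0.618 in DMSO, so its mean change rested on CSA and TAC. Airway RNA or reads in some libraries stay a candidate for it here too. At least 1 of the 4 groups differed for 10 genes: SAMD11, SFTPA1, ENSG00000196656, ID3, LINC02593, H2BC26, ID1, ENSG00000269706, GDF5 and SFTPA2. With the preset correlation alone 13 lists passed for the mean of the 3 inhibitors. ATF4 targets had 25 of 28 above 0 (camera adjusted p = 3.39e-08; adjusted p = 0.226 with an estimated correlation) and interferon-stimulated genes 33 of 37 below 0 (3.39e-08; adjusted p = 0.688 with an estimated correlation). The others were the slit diaphragm, BMP-SMAD, TGF-beta, interstitial matrix, basement membrane, focal adhesion, YAP, CREB, unfolded protein response and NRF2 lists, higher, and the NF-kB list, lower (camera adjusted p at most 0.0336; adjusted p = 0.688 with an estimated correlation). DNAJB9 was the 1 member of these lists to pass adjusted over the list alone (log2 0.43, SE 0.10). The BMP-SMAD call rested on TAC, where the score differed from DMSO by 0.415, against -0.07 in CSA and -0.009 in VCS. The interstitial matrix score differed by -0.125 in TAC, against 0.08 in CSA and 0.174 in VCS. Without DMSO 2 the slit diaphragm (0.145), TGF-beta (0.0845), interstitial matrix (0.378), basement membrane (0.446), focal adhesion (0.0965), YAP (0.245) and unfolded protein response (0.122) calls were lost. Without DMSO 3 the BMP-SMAD (0.182), CREB (0.276) and NRF2 (0.0902) calls were lost, and without DMSO 1 the NF-kB call (0.0689).

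Fold changes of the inhibitors were correlated across genes, but the 3 comparisons share the DMSO libraries. Over 19784 genes Pearson's r was 0.531 for CSA and TAC, 0.524 for CSA and VCS and 0.542 for TAC and VCS, and Spearman's rho was 0.469, 0.598 and 0.554, where groups simulated without change gave means of rho of 0.458, 0.455 and 0.454. Groups simulated without change that shared 3 controls gave means of r of 0.509, 0.5 and 0.503, and up to 0.550, 0.536 and 0.548. Among the 8812 genes with a mean log2 CPM of at least 4, r was 0.379 for CSA and TAC, 0.703 for CSA and VCS and 0.644 for TAC and VCS, where the simulated means were 0.499, 0.497 and 0.501 and the highest simulated values 0.574, 0.573 and 0.554. The simulated genes were drawn independently, while real genes move together, so the simulated values likely spread too little. An r outside their range therefore does not decide whether the inhibitors share a response. Genes are not independent replicates, so no p is given.

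CSA and VCS are structural analogs, given here at the same dose and time. VCS carries a modified side chain on a single amino acid residue of cyclosporine A. SFTPA1 was lower in CSA (0.201 ± 0.0767 against 3.34 ± 1.32 CPM; log2 -4.04, SE 0.50, adjusted p = 0.0217). ENSG00000196656 was at least 75.3-fold higher in CSA, with 734 counts against 0 (adjusted p = 0.0217). These were the 2 genes of 19784 that passed, and 503 had an unadjusted p under 0.05. For SFTPA1 airway RNA or reads in some libraries stay a candidate, and the assignment of reads to ENSG00000196656 is uncertain. For RCAN1 the difference was -0.13 (95% interval -0.32 to 0.06), for ID1 -0.10 (-0.49 to 0.29) and for SYNPO 0.08 (-0.19 to 0.35). For the 13610 expressed genes the median half-width of this interval was 0.288 on the log2 scale. It is an interval for a single gene, so a call over all genes mostly needs a larger difference. On simulated data for TAC against DMSO the test recovered 25.4% of genes changed 1.5-fold. That simulation held many more changed genes than passed here, which eases the adjusted threshold, so recovery here is likely lower.

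The ATF4 score was 5.96 ± 0.013 in CSA and 5.91 ± 0.078 in VCS, a difference of 0.058 (95% interval -0.035 to 0.15; exact permutation p = 0.4). The BMP-SMAD score differed by -0.061 (-0.271 to 0.149; exact permutation p = 0.6) and the NFAT target score by -0.095 (-0.342 to 0.151; exact permutation p = 0.4). Wider intervals were found for endothelial markers, -0.397 (-1.339 to 0.546; exact permutation p = 0.5), and histone genes, -0.221 (-0.658 to 0.215; exact permutation p = 0.6). With the preset correlation alone 4 lists passed. Unfolded protein response genes lay higher in CSA (22 of 25), and oxidative phosphorylation (35 of 46), histone (12 of 14) and ribosomal protein genes (34 of 40) lay lower, with camera adjusted p-values of 0.0153, 4.2e-05, 0.0172 and 4.2e-05. For all 4, adjusted p = 0.968 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. CSA replicate 3 stood apart in the ribosomal score, at 8.29 against 8.88 and 8.84 in the other CSA libraries. Without CSA 3 camera's direction turned for the oxidative phosphorylation, histone and ribosomal lists, and the adjusted p of the unfolded protein response list was 0.928; the ribosomal list then passed in the other direction (adjusted p = 0.00281). The call on SFTPA1 was lost without any CSA library, TAC 2 or VCS 2 (adjusted p up to 0.385), and without VCS 3 the count of genes was 7. With only these 2 groups in the fit 3 genes passed. DESeq2 gave 12 genes.

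CSA against TAC compares a cyclosporine with a macrolide. ID1 was lower in CSA (37.6 ± 10.4 against 91.1 ± 3.86 CPM; log2 -1.28, SE 0.18, adjusted p = 0.0282), as were ID3 (-0.74, SE 0.09, adjusted p = 0.0151) and SAMD11 (-1.69, SE 0.19, adjusted p = 0.0151). GDF5 (ENSG00000125965), which encodes a ligand of the BMP family, was higher in CSA (141.6 ± 18.3 against 75.6 ± 8.85 CPM; log2 0.91, SE 0.12, adjusted p = 0.0192) and overlaps GDF5OS. LINC02593 was lower in CSA (-1.62, SE 0.23). ENSG00000196656 had 734 counts in CSA and 1 in TAC (ratio 730, 95% counting interval 131 to 28900). Of 18 BMP-SMAD targets 2 were lower in CSA over all genes and 10 adjusted over the list alone (camera adjusted p = 2.33e-17; adjusted p = 0.00769 with an estimated correlation).

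Other lists separated CSA from TAC with the preset correlation alone. Unfolded protein response genes (24 of 25 above 0; 2 adjusted over the list alone), ATF4 targets (25 of 28), lysosomal genes (26 of 34), basement membrane genes (16 of 19; 4 adjusted over the list alone) and NF-kB genes (27 of 32; 1 adjusted over the list alone, VCAM1 at 0.91, SE 0.19) lay higher in CSA. So did interstitial matrix (21 of 26), focal adhesion (15 of 22), slit diaphragm (18 of 25) and parietal epithelial genes (10 of 15). Adjusted over the list alone, 1 slit diaphragm gene (INF2) and 1 parietal gene (VCAM1 again) were higher. Cell cycle (39 of 43 below 0), ribosomal protein (33 of 40) and histone genes (13 of 14) lay lower; adjusted over the list alone, the cell cycle genes CENPE and CDK1 and the histone gene H2BC5 were lower. INF2, CDK1 and H2BC5 were named after their values were seen. Camera adjusted p-values were at most 0.0384, and adjusted p = 0.428 or more with an estimated correlation for these 12 lists. NFAT targets did not pass as a list (camera adjusted p = 0.841), while adjusted over the list alone VCAM1 was higher in CSA and IL11, a cytokine gene named after its value was seen, lower. In all 6 genes and 13 lists passed, and 1488 genes had an unadjusted p under 0.05. No gene passed without CSA 2, CSA 3 or any TAC library, and 1 passed with only these 2 groups in the fit. The slit diaphragm list passed in 4 of 12 fits that left out a library (adjusted p 0.627 without TAC 3). Without TAC 3 the focal adhesion (0.627) and interstitial matrix (0.221) calls were also lost, and without CSA 3 the histone (0.531), parietal (0.186) and basement membrane (0.0792) calls, while the ribosomal list passed in the other direction without CSA 3 (adjusted p 0.00717). DESeq2 gave 51 genes, of which 3 were among the 6; it gave the other 3, SAMD11, LINC02593 and ENSG00000196656, no adjusted p, with log2 fold changes of -1.69, -1.63 and 9.40.

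TAC against VCS compares the macrolide with the cyclosporine A analog. ID3 was higher in TAC (139.4 ± 11.6 against 82.8 ± 4.27 CPM; log2 0.75, SE 0.09, adjusted p = 0.00926), as were SAMD11 (1.76, SE 0.20, adjusted p = 0.00926) and LINC02593 (1.87, SE 0.23, adjusted p = 0.00969). ID1 differed by 1.18 (SE 0.18) and did not pass (adjusted p = 0.0531). GDF5 was lower in TAC (-0.82, SE 0.12, adjusted p = 0.043), as was SFTPA1 (-4.26, SE 0.51, adjusted p = 0.00926). Of 18 BMP-SMAD targets 1 was higher over all genes and 9 adjusted over the list alone (camera adjusted p = 1.71e-21; adjusted p = 0.00337 with an estimated correlation).

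With the preset correlation alone 15 further lists passed between TAC and VCS. Cell cycle genes (40 of 43 above 0), TGF-beta targets (15 of 22), glucocorticoid receptor targets (15 of 20) and hypoxia genes (21 of 31) lay higher in TAC. Adjusted over the list alone, TGFBI (0.40, SE 0.10), SMAD7 (0.47, SE 0.13) and CENPE (0.40, SE 0.09) were higher. NF-kB genes (28 of 32 below 0) lay lower, and 3 of them passed adjusted over the list alone: VCAM1 (-0.96, SE 0.19), IL1B and the chemokine gene CCL2, the last 2 named after their values were seen. Interstitial matrix, basement membrane, focal adhesion, lysosomal, unfolded protein response, ATF4, calcium handling, parietal epithelial, endothelial and mitochondrially encoded genes also lay lower, with VCAM1 lower adjusted over the parietal list alone. NFAT targets did not pass as a list (camera adjusted p = 0.153), while adjusted over the list alone IL11 and F3, a tissue factor gene, were higher and VCAM1 lower. For the NF-kB list the camera adjusted p was 1.01e-10, and adjusted p = 0.14 with an estimated correlation. For the other 14 the camera adjusted p was at most 0.0249, and adjusted p = 0.34 or more with an estimated correlation. The mitochondrial list moved with VCS replicate 3, at a score of 12.3 against 11.2 in both other VCS libraries, and passed in the other direction without it (adjusted p = 0.0154). Without TAC 3 the total fell from 16 to 9 lists, with focal adhesion (0.509), endothelial (0.184), basement membrane (0.148), interstitial matrix (0.136), lysosomal (0.082), calcium (0.082) and unfolded protein response (0.0513) calls lost. The TGF-beta (0.476) and hypoxia (0.174) calls were lost without TAC 1, ATF4 (0.327) without VCS 2, glucocorticoid (0.215) without VCS 3 and parietal (0.228) without VCS 1. In all 5 genes passed, and 718 had an unadjusted p under 0.05. No gene passed without TAC 2 or VCS 2, or with only these 2 groups in the fit, and 12 passed without VCS 3. DESeq2 gave 37 genes, which held all 5. With replicate number as a block 41 genes passed.

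Markers of cells other than podocytes gave no call beyond the lists named. These lists covered parietal epithelial, mesangial and fibroblast, endothelial, renal tubule and leukocyte cells. No list was made for liver or airway epithelium, so the lists do not check for RNA of these. Against DMSO the leukocyte, renal tubule and mesangial lists had camera adjusted p-values from 0.305 to 0.896. Sign differed between median, mean and camera for the mesangial list in CSA and VCS, the leukocyte list in CSA and the tubule list in VCS. The median of the CREB list in CSA (-0.009) also differed in sign from its mean (0.13). None of these passed. MEOX1, a homeobox gene on the mesangial list, was at 10.85 ± 0.456 CPM in TAC and 10.3 ± 0.271 in VCS against 7.88 ± 0.401 in DMSO, and passed adjusted over that list alone in both (all-gene adjusted p = 0.426 and 0.963).

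A set of 41 genes of plasma proteins and metabolic enzymes, found after the results were seen by regrouping the CSA and VCS libraries, stood at 2 levels that crossed the groups. Its summed level was 614 to 744 CPM in CSA 2, CSA 3, the 3 TAC libraries and VCS 1, and 322 to 458 CPM in the 3 DMSO libraries, CSA 1, VCS 2 and VCS 3. The albumin gene ALB was at 266 and 223 CPM in CSA 2 and CSA 3 against 119 in CSA 1, and at 259 in VCS 1 against 113 and 119 in VCS 2 and VCS 3. The haptoglobin gene HP was at 98.2 CPM in VCS 1 against 41.9 and 38.4. Since the DMSO libraries were all low and the TAC libraries all high, the median log2 fold change of the set was 0.79 in TAC against DMSO, where 27 of the 41 had an unadjusted p under 0.05. None of the 41 passed in any comparison, by edgeR or by DESeq2. They were picked for differing within the CSA and VCS groups, and that spread enters the fit over all 12 libraries. Their absence from the calls therefore does not show that the calls are free of this structure.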

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

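The gene calls rest on 3 libraries per group, and most were lost when some single library was left out. That need not mark an outlying library. SAMD11 in TAC against DMSO was lost without any DMSO or TAC library (edgeR adjusted p up to 0.107). It was at 5.56 to 5.79 CPM in the TAC libraries and 1.82 to 2.12 in the DMSO libraries. The fits without the libraries numbered 3 and with robust estimation were chosen only after the results had been seen. Scaling on the ERCC spike-ins was not run, because the table held no spike-in rows. Libraries with the same replicate number were correlated across genes in their deviations from the group means. These correlations were all above 0 and exceeded 0.1 in 14 of 18 pairs, short of all, so the numbers were not taken to pair the samples. An effect shared by libraries of one number is not excluded by this. All 3 pairs exceeded it for CSA against DMSO (0.103 to 0.22), TAC against DMSO (0.108 to 0.377) and TAC against VCS (0.232 to 0.532), and the lowest in the other comparisons was 0.00694. In the order given below, 6, 5, 5, 4, 4 and 5 of 6 libraries correlated best with their own number. The libraries numbered 3 also had the largest mitochondrial share in every group. Libraries of the same number thus appear to share an effect. For TAC against DMSO the median SE was 0.172 without the block and 0.123 with it, so tests without the block likely miss changes. A reading per comparison, by which 3 of 6 comparisons passed, was taken first. The counts of the blocked fit had been seen before either reading was settled, and the more conservative one was kept. Where a count moved, the cause was not tested.

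Values below follow the order CSA, TAC and VCS against DMSO, CSA against TAC, CSA against VCS, TAC against VCS, mean of the inhibitors, any group. With no filter on low counts, 39923 genes were tested and 86, 131, 69, 87, 70, 101, 89 and 285 genes passed, and 22 lists for the mean. Up to the mean of the inhibitors, 13, 11, 7, 7, 7, 13 and 20 of the genes passing were ones that the filter removes. Most of the rise therefore came from genes that the filter keeps. DESeq2 gave 8, 34, 7, 51, 12, 37, 7 and 67 genes. Replicate number as a block gave 6, 41, 0, 65, 6 and 41 genes in the first 6 comparisons and 34 for any group, and 14 lists for TAC against DMSO. Genes with an unadjusted p under 0.05 were then 2254, 2597, 2179, 3145, 1244 and 1559 in these comparisons. Without the block they were 741, 919, 647, 1488, 503 and 718, where 989 are expected by chance. None of the 41 genes of plasma proteins and metabolic enzymes was among the calls of the block or of DESeq2. As these genes were picked for their spread within CSA and VCS, this does not show that the calls are free of that structure. With the block 6 BMP-SMAD targets and 1 NFAT target (IL11, higher) passed over all genes in TAC against DMSO, SFTPA2 and KRT5 passed, lower, in CSA and in TAC against DMSO, and ENSG00000196656 in VCS against DMSO had an adjusted p of 0.134. With only the groups compared, 2, 1, 0, 1, 3 and 0 genes passed in the first 6 comparisons. RLE size factors left every gene count unchanged.

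Without the 4 libraries numbered 3, genes passing were 0 for CSA against DMSO, 3 for TAC against DMSO, 1 for CSA against TAC, 6 for CSA against VCS, 9 for TAC against VCS and 0 for the mean. Lists passing were 6 for CSA against DMSO and 7 for CSA against TAC. In this setting 7 lists turned direction, with these mean log2 differences. For CSA against TAC they were slit diaphragm -0.01, focal adhesion -0.017 and ribosomal 0.094. For CSA against VCS they were unfolded protein response -0.006, oxidative phosphorylation 0.019 and ribosomal 0.056, and for TAC against VCS mitochondrially encoded 0.021. Robust estimation gave 0 genes for VCS against DMSO, 1 for CSA against VCS, 8 for TAC against VCS and 1 for the mean.

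With an estimated correlation, camera called 0, 1, 0, 1, 0 and 1 lists in the first 6 comparisons and 0 for the mean. Fry called 1, 1, 0, 1, 0 and 1, and 0 for the mean.

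With each library left out, genes passing ran from 0 to 2, 0 to 10, 0 to 8, 0 to 6, 0 to 7, 0 to 12, 0 to 4 and 1 to 23. Lists ran from 7 to 19, 7 to 17, 3 to 13, 9 to 18, 2 to 7, 9 to 19 and 7 to 18. Correlations of fold changes ran from 0.458 to 0.658 for CSA and TAC, 0.390 to 0.654 for CSA and VCS and 0.370 to 0.633 for TAC and VCS. Camera's direction turned in 5 leave-one-out results. The mean log2 difference of ribosomal genes in CSA against TAC ran from -0.194 without CSA 1 to 0.076 without CSA 3. In CSA against VCS, oxidative phosphorylation ran from -0.159 to 0.011, histone genes from -0.431 to -0.028 and ribosomal genes from -0.2 to 0.07, again without CSA 1 and CSA 3. Mitochondrially encoded genes in TAC against VCS ran from -0.463 without TAC 3 to 0.227 without VCS 3.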

Other observations

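Single members of lists that did not pass stood out in TAC against DMSO, each higher adjusted over its list alone and none over all genes. ANKRD1, a target of the mechanosensitive coactivator YAP, was at 394 ± 45.4 CPM against 292 ± 9.81 (SD, n = 3; log2 0.43, edgeR adjusted p = 0.537). SC5D, a sterol synthesis enzyme gene, was at 111 ± 8.57 CPM against 75.7 ± 5.02 (0.55, adjusted p = 0.207), while the median of its list was -0.027. SNAI1, a repressor of epithelial genes, was at 10.1 ± 1.64 CPM against 6.79 ± 0.425 (0.57, adjusted p = 0.579).

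The tests of depth or scaling and of a common calcineurin response below were chosen only after the BMP result had been seen; the predictions on unseen airway markers, on BMP targets outside the list and on the FAM156 sum were written before those values were read, except that whether the value of SFTPB had been seen was not recorded.

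Of 18 BMP-SMAD targets 14 were higher in TAC than in the 9 other libraries, with a median log2 difference of 0.52 against -0.085 to 0.083 in matched random lists. Depth or scaling would move genes of like level together, so it does not account for that value; the excess of 0.455 of TAC over the average of CSA and VCS restates the pattern, and as inhibition of calcineurin was not measured, a response common to the inhibitors stays open. The prediction of a rise in further SMAD1 and SMAD5 targets failed: 22 tested targets outside the list had a median of -0.057, at percentile 5.58 of random lists. That argues against a rise of these 22 genes as a set. The set also holds receptors and SMADs of the pathway (BMPR2, ACVRL1, SMAD1 and SMAD5) and antagonists of BMP (CHRDL1 and NBL1). It further holds endothelial and Notch genes, and the fall of the endothelial list had been seen. For these reasons it cannot decide whether SMAD1 and SMAD5 targets rose in general. A narrower response around ID1, ID3, SMAD6 and SMAD9 stays open, and these data do not separate a tacrolimus effect from the handling of the TAC cultures.

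SFTPA1, SFTPA2, KRT5 and KRT14 summed to 19.3 ± 9.1 CPM in DMSO and 22.8 ± 11.9 in VCS, against 2.74 ± 0.797 in CSA and 2.91 ± 1.18 in TAC (n = 3 each). RNA or reads of airway epithelium in some libraries is a candidate explanation. Of 37 unseen airway markers 19 lay above 0 in DMSO and VCS, and their median of 0.059 was at percentile 93.1 of random lists, which cannot tell. SFTPC (1.07) and BPIFB1 (1.19) went along through DMSO 1, VCS 1 and VCS 2 alone (51, 58 and 35 counts against 1 to 13 in the 9 others, and 34, 40 and 39 against 6 to 14), and KRT6B (1.46) with 21 to 56 counts in DMSO and VCS against 6 to 29, while SFTPB (-0.62) and SLPI (-0.68) went the other way. Among the airway markers already seen, KRT4 (2), LTF (1.64) and SHISA3 (1.31) also lay higher in DMSO and VCS. PKP1 (0.26) and MALL (0.19) were slightly higher, and TSPAN8 (-0.83) and MUC5B (-0.17) lower. LTF was highest in DMSO 1 and VCS 1 within these groups (100 and 120 counts), as was KRT5 (424 and 508). KRT4 was highest in DMSO 3 and VCS 3 (43 and 20 counts). Both carry-over and a change in the cells stay open.

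FAM156A and FAM156B, near-identical genes, moved in opposite directions between CSA and the other groups, a pattern named after the values were seen. Reads shared between the copies may explain it. The summed level ranged over 0.836 log2 units across the 12 libraries, which cannot tell, and the share of FAM156A in the sum ran from 18.9 to 91.4%.

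Other groupings of the same libraries were fitted, the real one counted among them. For CSA against DMSO, 1 of 10 splits gave as many genes as the real 2 (highest other 1) and 8 as many lists as 11 (highest other 17). For TAC against DMSO these were 1 for 7 genes (1) and 5 for 9 lists (20), and for VCS against DMSO 2 for 1 gene (7) and 7 for 8 lists (19). For CSA against TAC they were 2 for 6 genes (9) and 8 for 13 lists (18), for CSA against VCS 2 for 2 genes (41) and 10 for 4 lists (17), and for TAC against VCS 1 for 5 genes (1) and 4 for 16 lists (18). With 10 splits the share cannot be under 0.05. Of 60 splits, 24 gave as many lists as the 13 for the mean of the inhibitors (highest other 27), so other groupings do as well there. As many genes as its 2 came from 3 of the 60: the real split, TAC 1 to 3 against the rest (8), and CSA 3, TAC 2 and TAC 3 against the rest (18), so 1 of the 2 others is itself a treatment. For any group 2 of 60 gave as many genes as 10 (34), a share under 0.05. The 41 genes came from parting CSA 1, VCS 2 and VCS 3 from the other CSA and VCS libraries, which points to a structure of the samples that the groups do not describe. They are plasma protein and metabolic enzyme genes, at 614 to 744 CPM summed in CSA 2, CSA 3, TAC 1 to 3 and VCS 1 and 322 to 458 CPM in the 6 others; what set the 2 levels was not tested, and all TAC libraries were on one side and all DMSO libraries on the other.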
